A study of Mus musculus with 52 samples.

How the data were processed

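Peak lists of ChIP-seq libraries were analysed for 6 antibodies in mouse cells of 3 Mbd3 genotypes. The labels describe 52 samples, of which 43 have a peak list used here and 9 are input libraries without one. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, Bowtie 0.12.5 and MACS 1.4.1 and the genome build was mm9; which settings were used is not given in the sources used here. The value of each peak is the score deposited by the authors, taken from its range to be the caller's log-scaled p, and no list held a score below 50. These scores are the authors' own and were used only to describe, rank or filter peaks within a list, since ranks from lists of different lengths show no change. Peaks were called per library, with 1 list per library. Read totals and mapped depth are unknown, so a missing peak was read as not detected, and the number and width of peaks vary with depth and enrichment in ways that cannot be separated here. Median peak width ranged from 867 to 1970.5 bp among H3K4me3 lists and from 238 to 1013 bp among Mi2B lists.

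Samples were grouped by genotype, stage and antibody from their titles. For 6 Mbd3+/+ samples, 4 of them with a list, the stage label gives another day than the title: H3K27me3 (day 5), Mbd3 (day 6) and Mi2B (day 7) of day 4 and Mi2B (day 11) of day 8; the title was followed. The label of the +/+ day 8 H3K27me3 sample says that it repeats a record of the same biological sample. No group had more than 1 library, so there is no test across replicates.

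Positions were taken from the lists and are printed as 1-based mm9 coordinates. Peaks shared at least 1 bp to count as overlapping. Shares were computed as the peaks of a list that overlap another list, with 95% Wilson intervals, and differences between genotypes with 95% Newcombe intervals. Chance overlap came from 100 shuffles of the query peaks within the span that peaks covered on each chromosome, with no mask for unmappable sequence, so shuffled values are a low estimate. For sites defined by the absence of peaks in other lists, the shuffle does not apply that condition and can also be too high. iPS-gained sites were peaks of the +/+ iPS list that overlapped the flox/- iPS list and neither MEF list; for Mi2B, with no MEF list used here, the first condition alone applied. MEF-only sites were peaks of the +/+ MEF list that overlapped the flox/- MEF list and neither iPS list. As the site coordinates come from +/+ lists, the definition treats the genotypes alike in membership but not in peak edges.

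The groups, tests, named-region rule and most alternatives were fixed before the data were examined. These alternatives were a score of at least 100, 50% of the query peak covered, equal numbers of top peaks, peaks replaced by 250 bp either side of their midpoint, autosomes alone, and reference sites from each genotype's own lists. References made from the ES list or the +/+ iPS list alone, and equal numbers of top peaks for the overlap of H3K4me3 with H3K27me3 and for H3K27ac outside H3K4me3, and H3K27ac lists with the same number of top peaks on days 4 and 8 of a genotype, were added after the data were seen, as were the sites held in all MEF and iPS lists. Named regions are the 5 highest-scoring peaks of each genotype that overlap no peak of the other; the text gives those of H3K27ac on day 8 and Oct4 on day 4.

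The planned count of peaks at promoters of fixed gene lists was not run, because the gene table used here is of the GRCm38.p6 assembly and coordinates were not moved between builds. Gene names are therefore not given.

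The overlap code was tested on simulated data for the H3K27ac iPS-gained comparison, where true shares of 20.0% and 50.0% of 5996 sites were recovered as 20.0% and 50.0%. The simulated lists were exact copies of some of those sites, so this recovery was fixed in advance and checks the counting alone. Shifted edges, other widths and background peaks were not simulated. The overlap code was also checked on the flox/- day 8 H3K27ac list against bedtools 2.31.1, with 14670 of 21237 peaks overlapping by either method, and 11707 when 50% had to be covered by the other list. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.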

Results

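Chromatin was profiled by ChIP-seq while mouse embryonic fibroblasts (MEF) were driven towards induced pluripotent stem (iPS) cells by doxycycline-induced Oct4, Sox2, Klf4 and Myc. Cells of 3 Mbd3 genotypes were compared: Mbd3+/+, Mbd3flox/- (1 floxed and 1 null allele) and Mbd3-/-. Mbd3 is a subunit of the NuRD complex, which couples histone deacetylation to nucleosome remodelling, and Mi2B is its ATP-dependent remodeller. The lists analysed covered 6 antibodies, against H3K4me3 (a mark of promoters), H3K27ac (a mark of active promoters and enhancers), H3K27me3 (the Polycomb mark), Mbd3, Mi2B and Oct4. Stages were MEF, days 4 and 8 of doxycycline, iPS cells and, for Mbd3-/-, embryonic stem (ES) cells. Peaks were called per library, and each combination of genotype, stage and antibody had 1 library, so no difference between genotypes has a replicate check. The 43 lists held 928298 peaks, from 274 to 63888 per list. Intervals are 95% Wilson intervals for shares and Newcombe intervals for differences in percentage points. They cover the counting of peaks only, and read depth is unknown. Mbd3 lists of flox/- and -/- cells were not analysed here, so the genotype labels were not checked against Mbd3 itself.

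The first comparison asked how similar the 2 genotypes were at each stage. For H3K4me3 the overlap was uneven: 98.8% of the 17023 +/+ MEF peaks (98.6 to 99.0) and 97.4% of the 18684 +/+ day 4 peaks overlapped a flox/- peak, but 60.8% of flox/- MEF peaks and 65.5% of flox/- day 4 peaks overlapped a +/+ peak. In MEF, 81.6% of flox/- H3K27ac peaks overlapped a +/+ peak, against 56.7% on day 4 and 69.1% on day 8, and 87.3% in iPS cells. On day 8 only 43.0% of the 39463 +/+ H3K27ac peaks (42.5 to 43.5) had a flox/- counterpart. Day 4 Oct4 peaks were shared at 26.5% of 33755 in flox/- and 52.1% of 16785 in +/+ cells, and day 4 Mi2B peaks at 28.1% and 35.3%. At 1 bp of overlap the lowest shares were those of day 4 H3K27me3, 3.70% and 3.68%. The lowest share was that of +/+ iPS Mi2B peaks under 2 other settings. It was 2.91% with scores of at least 100 and 0.671% with 50% of the peak covered. At 1 bp of overlap all 34 shares, 2 directions for each of 17 pairs of lists, exceeded the highest of 100 shuffles. Equal numbers of top peaks cut only the +/+ lists of iPS Mi2B and Oct4, as the flox/- lists were shorter. The share of +/+ iPS Mi2B peaks found in flox/- then rose from 8.74% to 28.9%. That of +/+ iPS Oct4 peaks rose from 23.9% to 56.0%. With the searched +/+ list cut, the flox/- shares fell from 73.0% to 32.8% for Mi2B and from 84.7% to 56.0% for Oct4. Shares therefore depend on the length of the list searched and on which query peaks are kept. They also depend on peak width, since with fixed widths the flox/- H3K27ac shares were 60.8% in MEF, 37.1% on day 4, 42.5% on day 8 and 46.2% in iPS cells and the +/+ day 8 share 22.9%, the H3K4me3 shares in MEF were 69.2% of +/+ and 53.4% of flox/- peaks, and with 50% of the peak covered the flox/- shares were 40.5% for MEF H3K4me3 and 7.77% for day 4 Mi2B.

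H3K27ac differed between the genotypes in both directions by day 8. Sites gained in iPS cells, defined as 5996 H3K27ac peaks present in both iPS lists and neither MEF list, carried a peak at 14.4% in +/+ and 27.2% in flox/- cells on day 4. By day 8 the shares were 28.5% (27.4 to 29.7) and 57.1% (55.9 to 58.4), a difference of 28.6 percentage points (26.9 to 30.3). Mbd3-/- ES cells had a peak at 89.2% of these sites. At 29361 MEF-only sites, present in both MEF lists and neither iPS list, +/+ cells had a peak at 22.9% on day 4 and 29.3% on day 8, whereas flox/- cells had one at 13.7% and then 2.49% (2.32 to 2.68). The day 8 value in flox/- cells was below the mean of 5.91% for shuffled sites. MEF-only sites exclude every overlap with the iPS lists, so a list close to iPS cells can fall below shuffled sites by definition. The flox/- minus +/+ difference was -9.21 points (-9.83 to -8.59) on day 4 and -26.8 points (-27.4 to -26.3) on day 8. At 12480 sites with H3K27ac in all MEF and iPS lists, day 8 shares were 92.8% in +/+ and 81.1% in flox/- cells. At gained sites the difference was 6.57 points on day 4 with equal numbers of top peaks and 1.64 with 50% of the peak covered, against 12.8, and on day 8 10.8 with fixed widths, 15.0 with the ES list as reference and 15.7 with the +/+ iPS list, while the flox/- day 8 share was 37.1% with fixed widths and the +/+ rise between days fell from 14.2 to 6.04 points when both days had the same number of top peaks. At MEF-only sites the day 8 difference was -10.9 points with equal numbers, and the day 4 difference was -5.99 with fixed widths and -1.52 with each genotype's own reference, while the change in +/+ cells from day 4 to day 8 was -2.66 points with that same number and -0.138 with 50% of the peak covered.

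**Figure D1:**
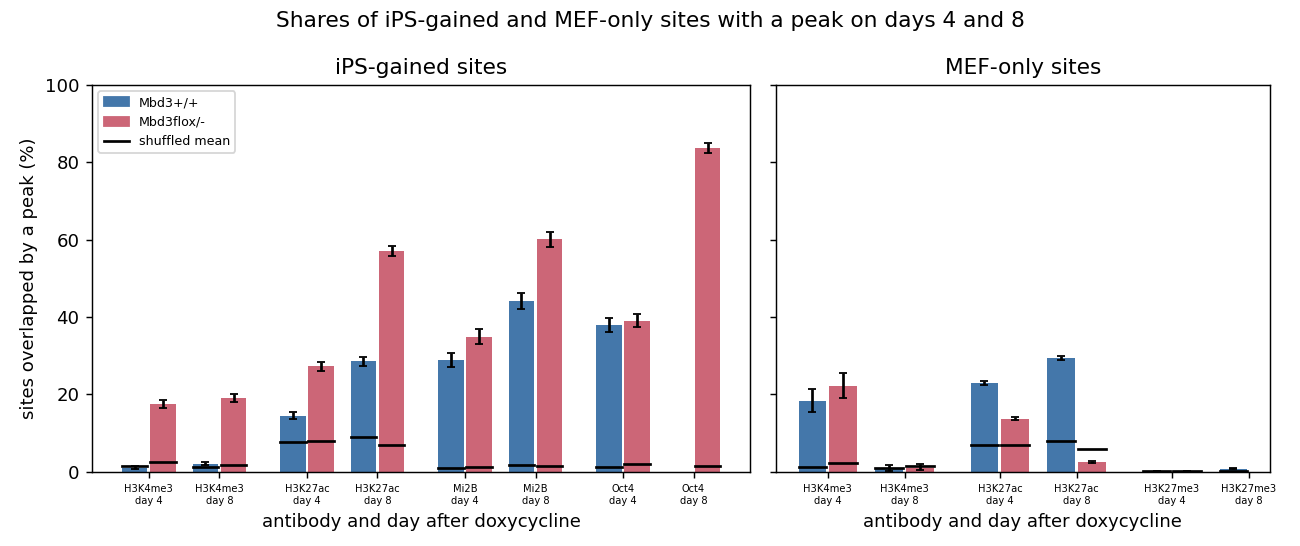
Bars give the percentage of reference sites overlapped by a peak, for Mbd3+/+ (blue) and Mbd3flox/- (red) lists by antibody and day after doxycycline, with 95% Wilson intervals as error bars and the mean of 100 shuffles as black lines; no bar is drawn where no list was analysed. H3K27ac at iPS-gained sites reached 57.1% in flox/- and 28.5% in +/+ cells on day 8, and at MEF-only sites 2.49% and 29.3%.

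Regions that carried H3K27ac in 1 genotype on day 8 were also compared across stages. The 5 flox/- peaks of highest score without a +/+ counterpart lay on chromosome 11 at 33424032 to 33445574, chromosome 10 at 70297973 to 70312566, chromosome 17 at 31908993 to 31923277, chromosome 18 at 75402864 to 75427265 and chromosome 3 at 83660233 to 83688186 (mm9). Each also had H3K27ac in flox/- iPS and -/- ES cells and a flox/- Oct4 peak on day 8. These peaks were 14285 to 27954 bp wide, against a list median of 3032 bp, so an overlap of 1 bp is easily reached. Other peaks of like width were not compared. They were not all new, however, since only that on chromosome 11 lacked H3K27ac in both MEF lists. The 5 highest +/+ peaks lay on chromosome 15 at 77081040 to 77091076, chromosome 4 at 88768526 to 88775906, chromosome 14 at 117323583 to 117328746, chromosome 5 at 144391149 to 144405815 and chromosome 7 at 56735600 to 56744917. All of these had H3K27ac in +/+ MEF, and those on chromosomes 4, 5 and 7 had none in any iPS or ES list, while those on chromosomes 14 and 15 did. Scores of 3100 were tied in the flox/- list, and tied peaks were taken in chromosome order. A score of exactly 3100 recurs across lists, although both day 8 H3K27ac lists reach 3233.06. It may be a fixed value, so the order by score near the top of a list is uncertain. No gene annotation of mm9 was used here, so nearby genes are not given.

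H3K4me3 at iPS-gained sites was detected more often in flox/- than in +/+ cells. Of 5407 such sites, 1.02% in +/+ and 17.4% in flox/- cells had a peak on day 4, and 2.07% and 19.0% had one on day 8. The differences were 16.4 points (15.4 to 17.5) and 16.9 points (15.8 to 18.0), and the -/- ES list covered 87.6%. The flox/- lists also covered more of the 15791 H3K4me3 sites held in all MEF and iPS lists, with 98.9% against 89.5% on day 4 and 88.6% against 78.9% on day 8. They spanned more sequence too, 49.0 against 21.1 Mb in MEF, 35.8 against 18.7 Mb on day 4 and 26.1 against 16.2 Mb on day 8. Since this was so before doxycycline, stronger flox/- libraries cannot be told apart from a difference in the mark at gained sites. MEF-only H3K4me3 sites were few, 621, and on day 8 had a peak at 0.644% in +/+ and 0.805% in flox/- cells, against shuffled means of 1.03% and 1.54%. Their day 4 shares, 18.2% and 22.1%, differed by 3.86 points with an interval that included 0 (-0.599 to 8.31). With the ES list as reference the gained differences were 7.66 and 5.18 points, with the +/+ iPS list 9.05 and 8.04, with each genotype's own reference 6.15 and 8.38, and on day 8 10.8 with scores of at least 100 and 10.9 with equal numbers of top peaks, while fixed widths gave +/+ shares of 6.45% and 7.59%. At MEF-only sites the day 4 difference took either sign, with -23.7 points for fixed widths, -4.14 for each genotype's own reference, 5.91 for 50% of the peak covered, 8.60 for the +/+ iPS list and 9.60 for scores of at least 100, and with fixed widths the 1146 sites had day 8 shares of 39.5% in +/+ and 28.6% in flox/- cells.

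H3K27ac outside H3K4me3, a proxy for enhancers, made up 80.9% of +/+ and 74.5% of flox/- MEF peaks. In iPS cells the shares were 57.9% and 51.3%, and in -/- ES cells 55.3%. On day 8 the share was 73.8% in +/+ and 58.4% in flox/- cells, a difference of -15.4 points (-16.2 to -14.6), whereas on day 4 it was 61.6% and 64.2%, a difference of 2.61 points (1.87 to 3.35). The day 8 difference turned to 1.97 points with equal numbers of top peaks, which also gave -6.72 points on day 4. That setting cut the H3K27ac lists alone. The flox/- H3K4me3 lists spanned more sequence, 49.0 against 21.1 Mb in MEF, 35.8 against 18.7 Mb on day 4 and 26.1 against 16.2 Mb on day 8. Wider H3K4me3 coverage alone can lower this share, and no setting gave the H3K4me3 lists equal numbers of peaks. The day 4 difference was -11.4 points with 50% of the peak covered, 1.29 with scores of at least 100 and 0.655 with fixed widths, with an interval that included 0 (-0.0410 to 1.35), and fixed widths gave -6.02 points on day 8.

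H3K27me3 lists were long in MEF, with 36232 peaks in +/+ and 35023 in flox/- cells, and in iPS cells, with 26114 and 13100. They were short in between, with 570 and 567 peaks on day 4 and 939 in +/+ cells on day 8. MEF-only H3K27me3 sites, 17165 in number, had a peak at 0.134% in +/+ and 0.157% in flox/- cells on day 4, and the 2551 iPS-gained sites had one at 0.0784% and 0.392%. The gained difference of 0.314 points turned to -0.201 with scores of at least 100 and to -1.62 with fixed widths. H3K4me3 peaks that also carried H3K27me3 were 8.52% in +/+ and 17.5% in flox/- MEF, a difference of 8.93 points (8.28 to 9.59). In iPS cells the shares were 15.5% and 14.1%, and in -/- ES cells 11.9%, all above the highest shuffled value. With 50% of the peak covered the shares were 6.59% in +/+ and 13.5% in flox/- MEF, and 3.87% and 6.99% in iPS cells. The order of MEF and iPS in +/+ cells therefore depends on the setting. The iPS difference of -1.43 points (-2.02 to -0.829) turned to 1.42 with scores of at least 100 and to 3.12 with 50% of the peak covered, and fixed widths reduced the MEF difference to 2.24. On days 4 and 8 the share was below 1% in each list, between 0.187% and 0.730%.

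Mbd3 occupancy was examined in +/+ cells, to ask where the protein sits as reprogramming proceeds. Mbd3 lists held 1177 peaks in MEF, 1944 on day 4 and 8657 in iPS cells. In iPS cells 77.7% of Mbd3 peaks (76.8 to 78.6) overlapped Mi2B, 85.8% H3K27ac, 46.3% Oct4, 22.6% H3K4me3 and 1.92% H3K27me3. On day 4 the overlap with Mi2B was 22.3% (20.5 to 24.2), with H3K27ac 38.4%, with H3K4me3 32.5% and with Oct4 15.7%. Shuffled Mbd3 peaks overlapped Mi2B at a mean of 2.08% in iPS cells and 0.401% on day 4. In MEF, 51.2% of Mbd3 peaks lay on H3K27ac, 15.8% on H3K4me3 and 12.9% on H3K27me3. Of MEF and day 4 Mbd3 peaks, 6.46% and 10.8% overlapped those of iPS cells, which does not tell moved sites from weak lists. With scores of at least 100 the day 4 overlap was 7.99% with Mi2B, 17.3% with H3K27ac and 5.43% with Oct4. In MEF that setting left 42 Mbd3 peaks, of which 16.7% lay on H3K27ac, 57.1% on H3K4me3 and 52.4% on Oct4 peaks from before doxycycline. The largest share of these 42 peaks lay on H3K27me3. Fixed widths lowered the H3K27ac overlap to 32.5% in iPS cells, 18.7% on day 4 and 22.9% in MEF, and the iPS overlap with H3K4me3 to 11.6%.

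At 1 bp of overlap, 72.2% to 81.5% of the Mi2B peaks of each list overlapped H3K27ac, against shuffled means of 3.06% to 6.47%. No other setting is given here for this share. The Mi2B sites of iPS cells were occupied more often in flox/- than in +/+ cells before that stage. Of 2358 Mi2B sites shared by both iPS lists, 28.8% in +/+ and 34.8% in flox/- cells were occupied on day 4, and 44.1% and 60.1% on day 8, differences of 5.98 points (3.32 to 8.63) and 16.0 points (13.2 to 18.8). With scores of at least 100 the day 4 difference was 3.38 points with an interval that included 0 (-3.62 to 10.4), and it was 17.1 with 50% of the peak covered and 13.4 with each genotype's own reference. The day 8 difference turned to -1.57 points with the ES list as reference and was 3.65 with the +/+ iPS list, 27.1 with scores of at least 100, 27.6 with 50% of the peak covered and 24.7 with equal numbers of top peaks.

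Mi2B was also found without Mbd3: 47.0% of the 26992 +/+ iPS peaks (46.4 to 47.6) and 68.9% of the 3462 flox/- iPS peaks overlapped the -/- ES list, against shuffled means of 1.93% and 1.21%. Of the +/+ iPS Mi2B peaks, those with an Mbd3 peak were found in -/- ES cells at 62.5% and those without at 41.8%, a difference of 20.7 points (19.4 to 22.0), a split chosen after the values were seen. The former were wider and stronger, with a median width of 1045 bp against 779 bp. Cell type and genotype differ together between iPS and ES cells. Equal numbers of top peaks lowered the flox/- iPS share in ES cells to 29.1%.

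Oct4 lists made before doxycycline held 274 peaks in +/+ and 489 in flox/- MEF, which serve as background. After 4 days they held 16785 and 33755. Day 4 Oct4 lay on chromatin already acetylated in MEF at 43.7% of +/+ peaks (43.0 to 44.5) and 26.6% of flox/- peaks (26.1 to 27.1), against shuffled means of 9.62% and 8.71%. Peaks with no H3K27ac in MEF or on day 4 made up 29.7% in +/+ and 43.5% in flox/- cells. By number, 7343 +/+ and 8982 flox/- peaks lay on MEF H3K27ac, and the flox/- list was the longer. A difference between genotypes in these shares therefore cannot be told apart from list length. Oct4 sites of +/+ iPS cells accounted for 19.0% of +/+ and 10.8% of flox/- day 4 peaks, and for 35.5% of the 19805 flox/- day 8 peaks (34.9 to 36.2). At the 2839 iPS-gained Oct4 sites, occupancy on day 4 was 37.9% in +/+ and 39.1% in flox/- cells, a difference of 1.13 points whose interval included 0 (-1.40 to 3.66). On day 8 flox/- cells had Oct4 at 83.7% of them (82.3 to 85.0); a +/+ day 8 Oct4 list was not analysed here. With equal numbers of top peaks the day 4 difference was -10.4 points, with 50% of the peak covered -3.12, with each genotype's own reference 8.53, and with the +/+ iPS list as reference 3.24 with an interval that excluded 0 (2.09 to 4.39). Fixed widths lowered the share on MEF H3K27ac to 17.2% in +/+ and 9.46% in flox/- cells.

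The highest Oct4 peaks of 1 genotype on day 4 were of 2 kinds. In +/+ cells the first was on chromosome 2 at 146125548 to 146126402, followed by chromosome 2 at 58448442 to 58449448, chromosome 16 at 38073750 to 38074500 and chromosome 17 at 5254492 to 5255599. These 4 had H3K27ac in the same cells and no peak in any other Oct4 list, while the next, on chromosome 8 at 94519416 to 94521669, was also in the +/+ iPS and flox/- day 8 lists. In flox/- cells, peaks on chromosome 19 at 45622012 to 45624012 and chromosome 12 at 109663800 to 109664564 were held on day 8. The other 3, on chromosome 2 at 98506279 to 98507605 and 98501983 to 98503266 and chromosome 9 at 35112390 to 35113419, were present in both MEF Oct4 lists, before doxycycline. In the same flox/- day 4 cells these 3 also had H3K4me3, H3K27me3, Mi2B and H3K27ac peaks. They lay in regions among the top 1% of peaks for at least 5 antibodies, so they are not particular to Oct4.

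Chromosome X held between 1.82% and 2.53% of peaks in the H3K27ac lists, between 1.98% and 3.15% in the H3K4me3 lists and at most 1.06% in the H3K27me3 lists. No list had more than 11 peaks on chromosome Y, and 11 lists had peaks on the mitochondrial genome. An H3K4me3 peak on chromosome Y at 345775 to 348500 was found in all flox/- H3K4me3 lists and the -/- ES list but in no +/+ one. Chromosome Y was not empty in +/+ H3K4me3 lists, with 2 peaks in MEF and 4 in iPS cells. Whether the lines differ in sex was not tested. Some regions were among the top 1% of peaks for many antibodies. A region of chromosome 17 from 35631199 to 35653797 and one of chromosome 2 from 98506220 to 98507920 each did so in at least 15 lists covering at least 5 antibodies, a lower bound because peaks tied at a score of 3100 were taken in chromosome order. The former, singled out after its values were seen, had a peak in 33 of the 43 lists. In the flox/- day 8 list 1 Oct4 peak spanned 17669 bp of it, in the +/+ MEF list 1 H3K27me3 peak spanned 17611 bp, and in the +/+ day 8 list 1 H3K27ac peak spanned 18203 bp. No H3K27ac or Oct4 peak lay there in either MEF genotype.

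**Figure D2:**
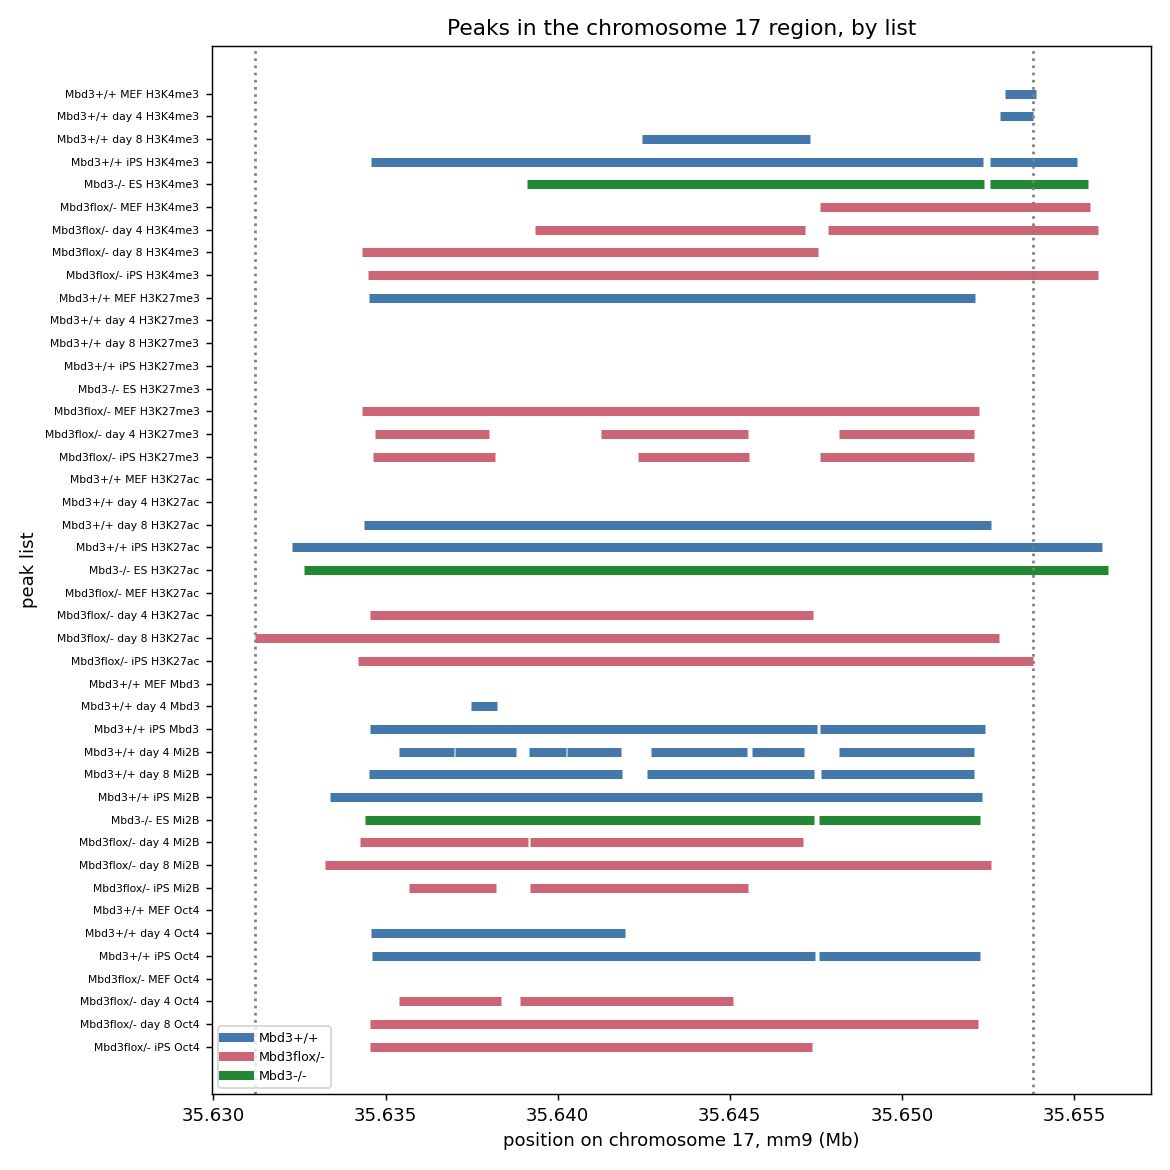
Each row is a peak list and each bar a peak of that list on chromosome 17 of mm9, with position in Mb on the horizontal axis and colour for genotype (blue Mbd3+/+, red Mbd3flox/-, green Mbd3-/-); dotted lines mark 35631199 and 35653797. A peak lies in the region in 33 of 43 lists.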

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

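The test of H3K27ac at sites held in all lists was added after the main values were seen, although what it should show was written before its own result; the test with equal numbers of top peaks was planned. Groups of 1 library allow no search for outlying samples. The differences given here were noted because the genotypes, or the stages, moved in opposite directions, and in each case the difference between them was not tested.

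From day 4 to day 8 the share of MEF-only H3K27ac sites with a peak changed by 6.42 points in +/+ cells and by -11.2 points in flox/- cells. These opposite directions were not kept when both days had the same number of top peaks, a setting chosen after the data were seen, with changes of -2.66 points (-3.33 to -2.00) in +/+ and -4.10 in flox/- cells, nor was the +/+ rise with 50% of the peak covered, at 21.2% and 21.1%. A shorter flox/- list does not account for all of the day 8 difference between genotypes, since with equal numbers of top peaks the flox/- minus +/+ difference was -10.9 points (-11.4 to -10.5), down from -26.8, so list length may carry part of it. A weaker flox/- library was tested at sites with H3K27ac in all MEF and iPS lists. The difference there was -11.7 points (-12.5 to -10.8), under 50% of that at MEF-only sites but close to that bound. The bound used the uncut -26.8, and -11.7 is no smaller than the -10.9 from equal numbers of top peaks. On day 8 +/+ cells had a peak at 92.8% of these sites and 29.3% of MEF-only sites, so both kinds need not be lost alike. The test therefore cannot exclude a weaker library. The iPS-gained sites differed by 28.6 points the other way, which a general loss of peaks does not give. A part from weaker detection therefore stays possible, and an effect of genotype stays open and untested, because genotype, clone and library cannot be separated with 1 library each.

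H3K27ac lists of flox/- cells held 1.402 times as many peaks as +/+ lists on day 4 and 0.538 times on day 8, while they covered 71.8 and 91.0 Mb against 91.8 and 97.1 Mb. Mi2B lists held 1.03 times as many peaks on day 4 and 0.564 times on day 8. H3K27ac outside H3K4me3 differed between genotypes by -6.44 points in MEF, 2.61 on day 4, -15.4 on day 8 and -6.63 in iPS cells. The H3K4me3 lists behind these shares were not matched in length. H3K4me3 with H3K27me3 differed by 8.93 points in MEF and -1.43 in iPS cells.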

How the results depend on the processing

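The references made from the ES or +/+ iPS list, and equal numbers of top peaks for H3K4me3 with H3K27me3 and for H3K27ac outside H3K4me3, and the same number of top peaks on both days, were chosen after seeing the data. Intervals from long lists are narrow, so most values left them: of 471 recomputed shares and differences, 132 stayed within the interval of the main value, 329 left it and 10 gave the opposite sign to a difference whose interval excluded 0. Differences whose interval included 0, such as those of Oct4 at iPS-gained sites on day 4 and of H3K4me3 at MEF-only sites, also took the other sign under some settings and are not among these 10. The H3K27ac differences between genotypes kept their direction under every setting run, at iPS-gained sites (1.64 to 13.2 points on day 4 and 10.8 to 42.7 on day 8) and at MEF-only sites (-13.3 to -1.52 and -28.1 to -10.9). So did the H3K4me3 differences at iPS-gained sites, between 5.18 and 19.0 points. Autosomes alone moved none of the overlaps between genotypes or of the differences at reference sites, and were not run for the other shares. Among shares that answer no comparison of their own, such as the share of peaks on X, scores of at least 100 lowered 33 and raised 9 of 59. Promoters of the fixed gene lists were not run under any setting. No paired analysis was possible because each group has 1 library. Depth, which is unknown, limits every statement on a missing peak. The cause was not tested for any of the changes below, which are in percent for shares and percentage points for differences.

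With scores of at least 100, the iPS-gained differences in percentage points that moved were 19.0 (H3K4me3 day 4), 10.8 (H3K4me3 day 8), -0.201 (H3K27me3 day 4), 27.1 (Mi2B day 8). Differences at MEF-only sites were 9.60 (H3K4me3 day 4), 1.52 (H3K4me3 day 8), -6.60 (H3K27ac day 4), -28.1 (H3K27ac day 8). H3K4me3 with H3K27me3 differed between genotypes by 9.61 (MEF), 1.42 (iPS). Its shares in percent were 4.14 (+/+ MEF), 13.8 (flox/- MEF), 8.93 (+/+ iPS), 10.3 (flox/- iPS), 7.78 (-/- ES). H3K27ac outside H3K4me3 differed between genotypes by -7.53 (MEF), 1.29 (day 4), -14.5 (day 8), -8.40 (iPS). Per list, this share was 78.2 (+/+ MEF), 70.6 (flox/- MEF), 54.9 (+/+ day 4), 56.2 (flox/- day 4), 71.4 (+/+ day 8), 56.9 (flox/- day 8), 55.8 (+/+ iPS), 47.4 (flox/- iPS), 52.5 (-/- ES). Of flox/- H3K4me3 peaks, the percentage found in +/+ was 63.9 (MEF), 74.4 (day 8), 89.6 (iPS). The reverse H3K4me3 share was 99.7 (MEF), 99.0 (day 4), 90.2 (day 8), 84.7 (iPS). Of flox/- H3K27ac peaks, the percentage found in +/+ was 83.0 (MEF), 60.8 (day 4), 71.3 (day 8), 89.9 (iPS). The reverse H3K27ac share was 75.6 (MEF), 71.7 (day 4), 40.3 (day 8), 51.6 (iPS). Of flox/- H3K27me3 peaks, the percentage found in +/+ was 66.0 (MEF), 5.88 (day 4), 48.6 (iPS). The reverse H3K27me3 share was 67.3 (MEF), 57.6 (iPS). Of flox/- Mi2B peaks, the percentage found in +/+ was 21.7 (day 4), 23.8 (day 8), 79.3 (iPS). The reverse Mi2B share was 25.5 (day 4), 17.5 (day 8), 2.91 (iPS). Of flox/- Oct4 peaks, the percentage found in +/+ was 91.9 (MEF), 24.8 (day 4), 87.3 (iPS). The reverse Oct4 share was 96.2 (MEF), 48.2 (day 4), 21.1 (iPS). Mbd3 peaks overlapped other lists in 57.1 (MEF H3K4me3), 16.7 (MEF H3K27ac), 59.5 (MEF H3K27me3), 52.4 (MEF Oct4), 7.99 (day 4 Mi2B), 24.9 (day 4 H3K4me3), 17.3 (day 4 H3K27ac), 0.958 (day 4 H3K27me3), 5.43 (day 4 Oct4), 85.3 (iPS Mi2B), 18.6 (iPS H3K4me3), 92.2 (iPS H3K27ac), 0.957 (iPS H3K27me3), 51.4 (iPS Oct4). Between iPS and ES, the Mi2B shares were 39.3 (+/+ iPS in -/- ES), 42.2 (-/- ES in +/+ iPS), 74.6 (flox/- iPS in -/- ES), 2.84 (-/- ES in flox/- iPS). Oct4 shares were 15.8 (+/+ day 4 in +/+ iPS Oct4), 39.7 (+/+ day 4 in +/+ MEF H3K27ac), 7.29 (+/+ day 4 in +/+ MEF H3K4me3), 8.77 (flox/- day 4 in +/+ iPS Oct4), 23.4 (flox/- day 4 in flox/- MEF H3K27ac), 11.5 (flox/- day 4 in flox/- MEF H3K4me3), 30.2 (flox/- day 8 in +/+ iPS Oct4), 22.1 (flox/- day 8 in flox/- MEF H3K27ac), 8.66 (flox/- day 8 in flox/- MEF H3K4me3). H3K27ac changes from day 4 to day 8 were 16.1 (+/+) and 32.9 (flox/-) at iPS-gained sites and 8.82 (+/+) and -12.6 (flox/-) at MEF-only sites.

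With 50% of the peak covered, the iPS-gained differences in percentage points that moved were 1.64 (H3K27ac day 4), 40.2 (H3K27ac day 8), 17.1 (Mi2B day 4), 27.6 (Mi2B day 8), -3.12 (Oct4 day 4). Differences at MEF-only sites were -12.7 (H3K27ac day 4), -18.0 (H3K27ac day 8). H3K4me3 with H3K27me3 differed between genotypes by 6.86 (MEF), 3.12 (iPS). Its shares in percent were 6.59 (+/+ MEF), 13.5 (flox/- MEF), 3.87 (+/+ iPS), 6.99 (flox/- iPS), 2.18 (-/- ES). H3K27ac outside H3K4me3 differed between genotypes by -12.1 (MEF), -11.4 (day 4), -12.0 (day 8), -14.3 (iPS). Per list, this share was 90.4 (+/+ MEF), 78.4 (flox/- MEF), 79.4 (+/+ day 4), 67.9 (flox/- day 4), 85.4 (+/+ day 8), 73.4 (flox/- day 8), 70.3 (+/+ iPS), 56.1 (flox/- iPS), 62.7 (-/- ES). Of flox/- H3K4me3 peaks, the percentage found in +/+ was 40.5 (MEF), 49.2 (day 4), 62.4 (day 8), 81.0 (iPS). The reverse H3K4me3 share was 96.5 (day 4), 91.3 (day 8), 72.5 (iPS). Of flox/- H3K27ac peaks, the percentage found in +/+ was 78.0 (MEF), 55.2 (day 4), 55.1 (day 8), 86.0 (iPS). The reverse H3K27ac share was 70.3 (MEF), 54.5 (day 4), 41.1 (day 8), 42.1 (iPS). Of flox/- H3K27me3 peaks, the percentage found in +/+ was 46.0 (MEF), 24.4 (iPS). The reverse H3K27me3 share was 51.1 (MEF), 34.1 (iPS). Of flox/- Mi2B peaks, the percentage found in +/+ was 7.77 (day 4), 18.4 (day 8). The reverse Mi2B share was 32.7 (day 4), 22.4 (day 8), 0.671 (iPS). Of flox/- Oct4 peaks, the percentage found in +/+ was 25.5 (day 4), 83.0 (iPS). The reverse Oct4 share was 3.28 (MEF), 46.2 (day 4). Mbd3 peaks overlapped other lists in 17.8 (day 4 Mi2B), 28.9 (day 4 H3K4me3), 1.29 (day 4 H3K27me3), 74.5 (iPS Mi2B), 17.6 (iPS H3K4me3), 84.3 (iPS H3K27ac), 0.578 (iPS H3K27me3), 40.2 (iPS Oct4). Between iPS and ES, the Mi2B shares were 35.5 (+/+ iPS in -/- ES), 42.8 (-/- ES in +/+ iPS), 66.6 (flox/- iPS in -/- ES), 2.05 (-/- ES in flox/- iPS). Oct4 shares were 17.03 (+/+ day 4 in +/+ iPS Oct4), 41.4 (+/+ day 4 in +/+ MEF H3K27ac), 8.41 (+/+ day 4 in +/+ MEF H3K4me3), 10.0 (flox/- day 4 in +/+ iPS Oct4), 24.7 (flox/- day 4 in flox/- MEF H3K27ac), 12.3 (flox/- day 4 in flox/- MEF H3K4me3), 31.0 (flox/- day 8 in +/+ iPS Oct4), 23.3 (flox/- day 8 in flox/- MEF H3K27ac), 10.0 (flox/- day 8 in flox/- MEF H3K4me3). H3K27ac changes from day 4 to day 8 were 6.39 (+/+) and 44.9 (flox/-) at iPS-gained sites and -0.138 (+/+) and -5.46 (flox/-) at MEF-only sites.

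With equal numbers of top peaks, the iPS-gained differences in percentage points that moved were 12.7 (H3K4me3 day 4), 10.9 (H3K4me3 day 8), 6.57 (H3K27ac day 4), 42.7 (H3K27ac day 8), 24.7 (Mi2B day 8), -10.4 (Oct4 day 4). Differences at MEF-only sites were -13.3 (H3K27ac day 4), -10.9 (H3K27ac day 8). H3K4me3 with H3K27me3 differed between genotypes by 7.44 (MEF), -3.69 (iPS). Its shares in percent were 16.0 (flox/- MEF), 17.8 (+/+ iPS). H3K27ac outside H3K4me3 differed between genotypes by -4.35 (MEF), -6.72 (day 4), 1.97 (day 8), -2.04 (iPS). Per list, this share was 78.8 (+/+ MEF), 54.9 (flox/- day 4), 56.4 (+/+ day 8), 53.3 (+/+ iPS). Of flox/- H3K4me3 peaks, the percentage found in +/+ was 76.6 (MEF), 71.7 (day 4), 78.5 (day 8), 80.1 (iPS). The reverse H3K4me3 share was 98.2 (MEF), 96.7 (day 4), 89.3 (day 8), 84.6 (iPS). Of flox/- H3K27ac peaks, the percentage found in +/+ was 78.5 (MEF), 67.9 (day 4), 55.9 (day 8), 82.4 (iPS). The reverse H3K27ac share was 78.3 (MEF), 61.5 (day 4), 59.0 (day 8), 64.1 (iPS). Of flox/- H3K27me3 peaks, the percentage found in +/+ was 58.2 (MEF), 38.5 (iPS). The reverse H3K27me3 share was 62.0 (MEF), 55.2 (iPS). Of flox/- Mi2B peaks, the percentage found in +/+ was 27.3 (day 8), 32.8 (iPS). The reverse Mi2B share was 29.8 (day 8), 28.9 (iPS). Of flox/- Oct4 peaks, the percentage found in +/+ was 14.6 (MEF), 35.9 (day 4), 56.0 (iPS). The reverse Oct4 share was 35.62 (day 4), 56.0 (iPS). Between iPS and ES, the Mi2B shares were 45.1 (+/+ iPS in -/- ES), 47.6 (-/- ES in +/+ iPS), 29.1 (flox/- iPS in -/- ES), 26.5 (-/- ES in flox/- iPS). Oct4 shares were 22.1 (+/+ day 4 in +/+ iPS Oct4), 15.9 (flox/- day 4 in +/+ iPS Oct4), 46.2 (flox/- day 8 in +/+ iPS Oct4).

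With peaks of fixed width, the iPS-gained differences in percentage points that moved were 15.1 (H3K4me3 day 8), 10.9 (H3K27ac day 4), 10.8 (H3K27ac day 8), -1.62 (H3K27me3 day 4). Differences at MEF-only sites were -23.7 (H3K4me3 day 4), -10.9 (H3K4me3 day 8), -5.99 (H3K27ac day 4), -19.7 (H3K27ac day 8). H3K4me3 with H3K27me3 differed between genotypes by 2.24 (MEF), -4.10 (iPS). Its shares in percent were 2.22 (+/+ MEF), 4.46 (flox/- MEF), 11.1 (+/+ iPS), 6.98 (flox/- iPS), 6.98 (-/- ES). H3K27ac outside H3K4me3 differed between genotypes by -4.73 (MEF), 0.655 (day 4), -6.02 (day 8), -4.44 (iPS). Per list, this share was 85.9 (+/+ MEF), 81.2 (flox/- MEF), 70.3 (+/+ day 4), 70.9 (flox/- day 4), 80.1 (+/+ day 8), 74.1 (flox/- day 8), 72.0 (+/+ iPS), 67.5 (flox/- iPS), 66.0 (-/- ES). Of flox/- H3K4me3 peaks, the percentage found in +/+ was 53.4 (MEF), 59.0 (day 4), 66.1 (day 8), 79.0 (iPS). The reverse H3K4me3 share was 69.2 (MEF), 68.5 (day 4), 76.3 (day 8), 64.0 (iPS). Of flox/- H3K27ac peaks, the percentage found in +/+ was 60.8 (MEF), 37.1 (day 4), 42.5 (day 8), 46.2 (iPS). The reverse H3K27ac share was 54.2 (MEF), 51.8 (day 4), 22.9 (day 8), 36.0 (iPS). Of flox/- H3K27me3 peaks, the percentage found in +/+ was 31.3 (MEF), 6.17 (day 4). The reverse H3K27me3 share was 30.3 (MEF), 5.96 (day 4), 31.4 (iPS). Of flox/- Mi2B peaks, the percentage found in +/+ was 34.0 (day 8), 66.8 (iPS). The reverse Mi2B share was 33.9 (day 4), 20.2 (day 8), 8.19 (iPS). Of flox/- Oct4 peaks, the percentage found in +/+ was 25.8 (day 4). Mbd3 peaks overlapped other lists in 13.2 (MEF H3K4me3), 22.9 (MEF H3K27ac), 5.18 (MEF H3K27me3), 27.7 (day 4 Mi2B), 18.7 (day 4 H3K27ac), 4.42 (day 4 H3K27me3), 71.1 (iPS Mi2B), 11.6 (iPS H3K4me3), 32.5 (iPS H3K27ac), 44.5 (iPS Oct4). Between iPS and ES, the Mi2B shares were 44.0 (+/+ iPS in -/- ES), 41.1 (-/- ES in +/+ iPS). Oct4 shares were 17.2 (+/+ day 4 in +/+ MEF H3K27ac), 6.34 (+/+ day 4 in +/+ MEF H3K4me3), 9.46 (flox/- day 4 in flox/- MEF H3K27ac), 5.75 (flox/- day 4 in flox/- MEF H3K4me3), 9.04 (flox/- day 8 in flox/- MEF H3K27ac), 4.85 (flox/- day 8 in flox/- MEF H3K4me3). H3K27ac changes from day 4 to day 8 were 9.55 (+/+) and 9.47 (flox/-) at iPS-gained sites and 4.73 (+/+) and -8.94 (flox/-) at MEF-only sites.

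With each genotype's own reference, the iPS-gained differences in percentage points that moved were 6.15 (H3K4me3 day 4), 8.38 (H3K4me3 day 8), 32.1 (H3K27ac day 8), 13.4 (Mi2B day 4), 22.7 (Mi2B day 8), 8.53 (Oct4 day 4). At MEF-only sites the differences were -4.14 (H3K4me3 day 4), -1.52 (H3K27ac day 4), -18.0 (H3K27ac day 8). Over time, H3K27ac in +/+ cells changed by 10.8 at iPS-gained sites and 5.46 at MEF-only sites.

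With the ES reference, the iPS-gained differences in percentage points that moved were 7.66 (H3K4me3 day 4), 5.18 (H3K4me3 day 8), 9.97 (H3K27ac day 4), 15.0 (H3K27ac day 8), -1.57 (Mi2B day 8). At MEF-only sites the differences were -10.04 (H3K27ac day 4), -25.7 (H3K27ac day 8). Over time, H3K27ac changed by 7.89 (+/+) and 12.9 (flox/-) at iPS-gained sites and -9.21 (flox/-) at MEF-only sites.

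With the +/+ iPS reference, the iPS-gained differences in percentage points that moved were 9.05 (H3K4me3 day 4), 8.04 (H3K4me3 day 8), 10.7 (H3K27ac day 4), 15.7 (H3K27ac day 8), 3.65 (Mi2B day 8). At MEF-only sites the differences were 8.60 (H3K4me3 day 4), 1.58 (H3K4me3 day 8). Over time, H3K27ac changed by 10.6 (+/+) and 15.6 (flox/-) at iPS-gained sites and -11.7 (flox/-) at MEF-only sites.

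With the same number of top peaks on both days, H3K27ac changed from day 4 to day 8 by 6.04 (+/+) and 41.8 (flox/-) at iPS-gained sites and by -2.66 (+/+) and -4.10 (flox/-) at MEF-only sites. The rise in +/+ cells at MEF-only sites was thus reversed, while both rises at iPS-gained sites were kept. Equal numbers of top peaks within a day leave the days unequal, so that setting was not read across days.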

Other observations

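The tests of the chromosome 17 region were chosen only after its peaks were seen, as was the count of H3K27me3 peaks shared with other antibodies, whose separate overlaps were already known. For the other tests the outcome to look for was written before their results, although the overlap of all day 4 Oct4 and H3K27ac peaks had been seen.

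Day 4 Oct4 and H3K27ac coincided at sites of both kinds. Of the iPS-gained H3K27ac sites, those with a day 4 Oct4 peak of the same genotype were acetylated on day 4 at 61.2% in +/+ cells (852 sites) and 68.8% in flox/- cells (1328 sites), against 6.63% and 15.3% without one. By day 8 sites without a day 4 Oct4 peak reached 20.4% in +/+ and 50.7% in flox/- cells, and sites with one 77.7% and 79.5%. At MEF-only sites with a day 4 Oct4 peak, acetylation on day 8 was 77.3% in +/+ cells (2172 sites) and 8.68% in flox/- cells (2317 sites), after 82.7% and 62.3% on day 4. Without such a peak it was 25.5% and 1.96% on day 8, after 18.1% and 9.51% on day 4. The sites of the 2 genotypes differ here, and their day 8 H3K27ac lists held 39463 and 21237 peaks. These shares were not recomputed with equal numbers of top peaks. Within 5 groups of site width, the smaller of the day 4 differences in the 2 genotypes was 51.2 points, but this decides nothing about the gained sites, because 65.9% of +/+ and 51.3% of flox/- day 4 Oct4 peaks were already known to lie on H3K27ac when the bound of 5 points was set. The same held for day 4 Mi2B peaks, with 71.9% against 11.2% in +/+ cells, and for Oct4 at MEF-only sites, so the association is not specific and says nothing of order or cause.

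The short H3K27me3 lists of days 4 and 8 could come from libraries with low enrichment or reflect fewer marked sites. Of 500 top-scoring sites held in all MEF and iPS lists, 41.4% had a peak in +/+ cells on day 4, 18.4% in flox/- cells on day 4 and 30.0% in +/+ cells on day 8, above the 10% set as the bound for failed enrichment in each list. Over all 2519 such sites the shares were 13.3%, 6.75% and 11.2%. The flox/- day 4 share was then under 10%, although the bound was set for the 500. Of the listed peaks, 97.2%, 58.7% and 68.7% lay on H3K27me3 of MEF or iPS cells, against shuffled means of at most 5.68%, so the lists are not random positions. This overlap cannot tell the mark from regions shared by many antibodies. Such regions on chromosomes 2 and 17 have peaks in the MEF H3K27me3 lists too. Of the flox/- day 4 peaks, 31.6% overlapped a peak of another antibody in those cells, against 14.7% in +/+ cells on day 4 and 11.5% on day 8. The flox/- value lay under its bound, but this decides nothing about regions shared by antibodies. The separate overlaps were already known when that bound was set. A lower depth or partial loss of enrichment stays open, because depth is unknown, and a change in the mark was not tested.

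The chromosome 17 region described above had peaks of all 6 antibodies in +/+ lists and of all 5 antibodies with a list in flox/- cells. In -/- cells it had peaks of 3 antibodies. The -/- H3K27me3 list had none there, and no -/- Mbd3 or Oct4 list was analysed here. Per the series record the +/+ clone carries an Oct4-GFP reporter without the proximal enhancer and the flox/- and -/- cells carry the complete reporter, so extra copies of such a sequence are a candidate explanation, although no gene was assigned to these coordinates here. Top 1% peaks of Mi2B, Oct4 or H3K27me3 outside MEF were found there in 7 of 10 flox/- and -/- lists and 4 of 8 +/+ lists, 20.0 points apart, but this decides nothing: ranks in lists of 567 to 33755 peaks cannot be compared, lists of the same cells are not independent, and every genotype carries a reporter. Occupancy of the endogenous locus that differs by genotype cannot be told apart from extra copies either: the prediction as first written counted any peak in a flox/- MEF list of Oct4 or H3K27me3 against it, and 1 such list, that of H3K27me3, had one, but this was set aside after the result was seen because 1 +/+ list had the same peak. Input lists would bear on it and were not analysed here.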
